A study of Mus musculus with 192 samples.

How the data were processed

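The study measured RNA from small cubes of mouse brain, called voxels, on 2-colour arrays against a common reference of whole mouse brain RNA. The animals were C57BL/6 males of postnatal day 56, and each array carried 1 voxel sample in one channel and the reference in the other. Each voxel was named by a grid row, A to G, and a grid column, 1 to 11, of a section of the brain. The labels gave 68 such positions and no anatomical directions, so rows and columns are used here as named. There were 192 arrays in 3 independently harvested datasets of 59, 68 and 65 arrays. Of the positions, 56 were measured in all 3 datasets and 12 in 2 of them. Per the labels, voxel RNA was labelled with Cy3 in datasets 1 and 3 and with Cy5 in dataset 2, so dye orientation and dataset cannot be told apart within one dataset. Per the labels' protocols, total RNA was extracted with Trizol and reverse transcribed before dye coupling. The scanner, the background correction and the normalization are not given in the sources used here.

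The authors deposited a single table of log2 ratios with 20847 rows and 192 columns, and no spot intensities were used here. Its lowest value, -6.64 (the log2 of a ratio of 0.01), occurred 19322 times, which is 0.483% of the values, and acted as a floor. A further 1.93% of values were missing, and the highest value was 18.65. Array medians lay between -0.08 and 0.13. In the deposited log2 ratios 99.9% of rows had a median over all arrays within 0.001 of 0, and nearly all of the 6716 rows with an odd number of values (99.96%) held an exact 0. The rows had therefore been centred on their own median. This centring removes the level of a gene in the section relative to whole brain, so the planned comparison of the section with whole brain could not be made, and values here compare positions with each other only. Rows were named through the platform annotation: 13164 had 1 gene symbol, 317 several, 7299 none and 47 a symbol of another species. Of those with 1 symbol, 12982 matched the mouse gene table and 0 symbols changed.

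The labels give the dyes but not which channel is the numerator. The datasets were taken to run the same way, because the median correlation of a gene's maps was above 0 in each pair of datasets, although small (0.0550, 0.0276 and 0.00369 over all genes). The maps of the striatal, cortical and myelin lists, fixed beforehand, had a Spearman rho of at least 0.596 in each pair. The lowest correlation of any 2 arrays of one dataset was -0.573 (median 0.170), and 0.676% of such pairs lay under -0.3. The direction was kept because the labels state the dyes and different brain regions could oppose each other. That positive values mean more RNA in the voxel is likely but not stated. The basis was chosen after the values were seen. Whole brain is called the control, and striatal marker genes and the choroid plexus gene Ttr had high values in compact blocks of positions. Of the 3 measured choroid plexus genes only Ttr differed among positions. The planned check of the direction, which set the levels of cerebellar and hindbrain markers against striatal ones, could not be computed on centred rows. The highest correlation between any 2 arrays was 0.826, so no array was taken for a duplicate of another.

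Floor values were treated as not measured. Each array was centred on its median over the rows measured on every array, a shift of at most 0.353. Rows measured on at least 80% of the arrays of every dataset were kept, 20 control rows were left out, and rows sharing 1 symbol were averaged. This gave 15608 features, called genes here, of which 8447 had a symbol, 7161 had none and 2904 were averages of several rows. Rows of one gene did not always follow each other: the 4 rows of Sparc correlated at between 0.144 and 0.845, the 3 rows of Peg3 at between -0.188 and 0.718 and the 2 rows of Chn1 at 0.901. Arrays give no read depth, so the number of arrays limits the precision. The dataset is the replicate in every zone comparison, with n = 3.

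Differences among positions were tested with limma's moderated F test with the dataset as a block. The dataset numbers name independent harvests, so they pair the arrays. The deviations of arrays of one dataset from the position means correlated at a median of 0.237 over 7555 genes measured on every array (0.189, 0.260 and 0.252 in datasets 1 to 3). For arrays of different datasets the median was -0.120. That value follows from the first, because the deviations at a position add up to 0 over its datasets. A gene's level that differs by dataset or dye can give the first value, so it shows no more than that arrays of a dataset share deviations. Zones were compared with limma on 1 value per dataset and gene, the difference of the zone means within the dataset, two-sided against 0. The zones were rows A-B against rows F-G, columns 5-7 against columns 1-3 and 9-11, columns 1-5 against columns 7-11 in mirror pairs of positions, and the perimeter of the grid against its interior. A perimeter position had at least 1 neighbouring place in the grid that no dataset measured. All p-values were adjusted by Benjamini-Hochberg, and calls were made at 0.05.

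The 24 gene lists were striatal projection neuron, cortical excitatory neuron, septum and basal forebrain cholinergic, hypothalamus and preoptic area, thalamus, hippocampus, cerebellum, midbrain and hindbrain, olfactory bulb, inhibitory neuron, pan-neuronal, myelin and oligodendrocyte, astrocyte, microglia, vascular, meninges, choroid plexus, ependyma, blood, immature neuron and proliferation, immediate early, heat shock, ribosomal protein and oxidative phosphorylation. Lists with at least 3 measured genes, 22 in all, were tested within each zone comparison. This was done with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. The second test works from 3 values per gene and has little power. A call lost in it does not by itself point to correlated genes. For 4 lists, each gene was also tested for following the list's map. Its values in one dataset were correlated over positions with the list mean in the other datasets, the gene itself left out, and limma was run on the Fisher z of the 3 correlations. The 3 values of a gene share list maps and are not fully independent.

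Lists, zones, tests and the rule for named genes were fixed before the data were examined. The rule named the 12 genes with the largest F. For each zone comparison it took up to 6 called genes in each direction with the same sign in all 3 datasets, or the 3 with the smallest p in each direction where none passed. It added up to 4 members of each list with the largest absolute value, and the 8 genes outside each list that followed its map most closely. Clone names were skipped. Genes outside the rule are said to be chosen after their values were seen. The alternatives covered the block, the dye, the array centring, the filter on missing values, the averaging of rows, array weights, the positions used, trends in place of zones, rank correlations and leaving out each dataset. Alternatives added after the data were seen kept the floor values, limited values to within 3 of 0, left out the array of position G8 in dataset 3 or 6 arrays of row D in dataset 2, or left each member out of a list's map in turn.

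The steps were tested on simulated data of 15608 genes. For positions and list maps, values were drawn for the arrangement of the real arrays. For the zone comparisons no arrays were simulated: 3 independent values per gene were drawn, with the moderated spread of the real datasets. Genes did not vary together in these values, so recovery in the real zone comparisons can be lower. In the real middle columns Ppp1r1b differed by -1.60 without passing limma's test (adjusted p = 0.0868). The position test recovered 90% of genes whose positions varied with an SD of 0.5 and 100% at 1. A zone difference of 1 was recovered for 94% of genes between rows A-B and rows F-G and for 100% in the other 3 zone comparisons, and a difference of 0.5 for 10%, 94%, 94% and 96% in the order given above. Calls without a simulated effect were 11 of 201 for positions and 14 of 166, 23 of 220, 10 of 207 and 15 of 213 for the zone comparisons in that order, so more than the 5% aimed at for positions, rows, middle columns and perimeter. R 4.3.3, limma 3.58.1 and the data.table package (1.17.8) were used, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.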

Results

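Expression was measured in voxel samples of mouse brain, each on its own array against whole brain RNA, at 68 positions of a grid of rows A to G and columns 1 to 11. Dataset 1 had 59 arrays, dataset 2 had 68 and dataset 3 had 65. The typical spread of an array, the median absolute deviation of its log2 ratios, was 0.313, 0.241 and 0.335 in datasets 1 to 3, and a median of 1.07%, 1.65% and 0.955% of values per array was missing. The array of position G8 in dataset 3 had the most missing, 33.3%. Values are centred log2 ratios, and higher values likely mean more RNA in the voxel. Each value is a mean with its SD over the datasets, with n = 3 unless given as n = 2. The number of arrays limits the precision of a position mean.

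The first comparison asked which genes differed among the positions. Ppp1r1b, whose product DARPP-32 relays dopamine signals in striatal projection neurons, was highest at D9 (2.60 ± 0.70) and lowest at B5 (-2.58 ± 0.20, n = 2), with an F of 7.41 (adjusted p = 7.1e-19). It formed 2 separate islands, with 2.39 ± 0.43 at C3, 2.30 ± 0.69 at E4 and 2.30 ± 0.41 (n = 2) at B3 in the other. Ttr, the thyroid hormone carrier secreted by the choroid plexus, reached 3.72 ± 0.61 at E7, 3.69 ± 0.53 at E6 and 3.01 ± 0.41 at E4, along the middle of row E (F = 4.58, adjusted p = 2.8e-11). Vxn, which promotes neuronal differentiation, was highest at F8 (2.04 ± 0.51) and lowest at C7 (-2.62 ± 2.37, n = 2), with an adjusted p of 1.3e-17. Ndn, an imprinted gene of hypothalamic neurons, reached 1.92 ± 0.10 at A5 and 1.76 ± 0.28 at A6 (adjusted p = 3.2e-16).

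Among all 15608 genes, 768 (4.92%) differed among positions, 557 of them with a symbol, and 2078 had an unadjusted p under 0.05 where 780.4 would be expected by chance. The growth cone gene Gap43 had the largest F of the genes with a symbol (10.7, adjusted p = 8.4e-26), with 1.24 ± 0.43 at C6 and -1.53 ± 0.60 (n = 2) at G2. Bcas1, a gene of myelinating oligodendrocytes, was highest at D4 (1.63 ± 0.27) and lowest at C1 (-1.40 ± 0.30). Chn1, a regulator of Rac signalling in neurons, ranged from 0.93 ± 0.15 (n = 2) at F10 to -1.73 ± 0.18 at A6. Dkk3, a secreted protein of the Dickkopf family, was highest at G5 (1.69 ± 0.01, n = 2). Nrgn, which binds calmodulin in dendritic spines, was highest at E11 (1.19 ± 0.25), and the growth factor binding protein Igfbp4 at F3 (1.63 ± 0.55). The transcription factor Egr1, induced by neuronal activity, ranged from 1.37 ± 0.06 (n = 2) at E3 to -2.78 ± 1.48 at A6. Basp1, a membrane protein of growing axons, was highest at F4 (0.76 ± 0.23). Sparc, a matrix protein, was highest at B5 (1.25 ± 0.13, n = 2), and the imprinted zinc finger gene Peg3 at A6 (0.90 ± 0.13). With each row of the table tested on its own, the row of Sparc with the largest p had an F of 1.05 and that of Peg3 an F of 0.932, neither passing. The median range of position means of the genes called was 1.71, with 90% between 1.03 and 3.60. With positive values taken as more RNA in the voxel, their highest position lay in rows C-E for 356, in rows A-B for 229 and in rows F-G for 183. Lowest positions, which would matter if the ratio ran the other way, were not tallied. Of all genes 6552, 4059 and 4997 had their highest position in these rows in the same order, and rows C-E hold 33 of the 68 positions. The count was 366 without the dataset as a block, 1161 with quantile normalization, 2573 with array weights, 324 without dataset 1 and 213 without dataset 2.

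**Figure D1:**
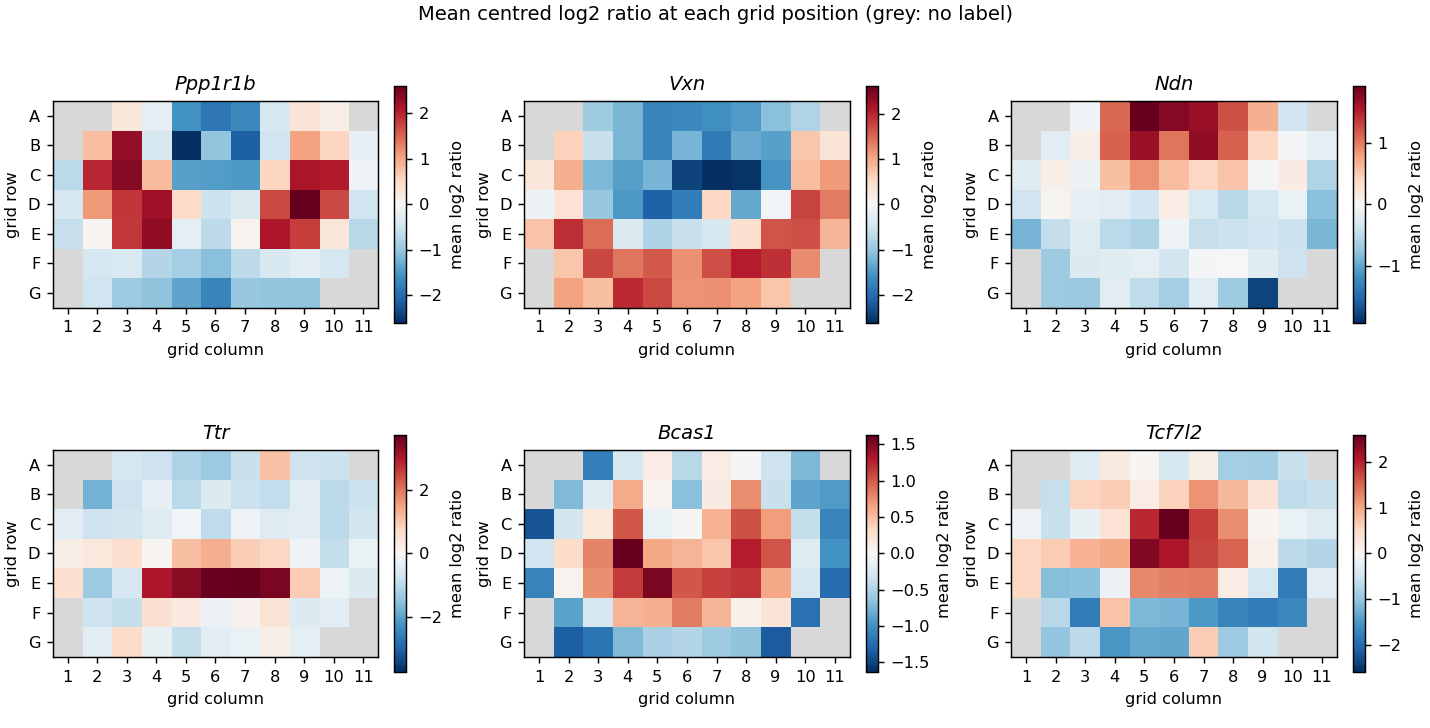
Mean centred log2 ratio of 6 genes (colour, own scale for each gene) at each grid position, with grid columns 1 to 11 across and grid rows A to G down; grey places have no label. Ppp1r1b peaks at D9 (2.60), Vxn at F8 (2.04), Ndn at A5 (1.92), Ttr at E7 (3.72), Bcas1 at D4 (1.63) and Tcf7l2 at C6 (2.58).

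Each marker list was averaged at each position over its measured genes, which were only part of the list. Measured were 7 of 20 striatal, 4 of 20 cortical, 4 of 9 thalamus, 3 of 23 hypothalamus, 3 of 14 choroid plexus and 4 of 22 myelin genes. The striatal list mean was highest at D9 (1.40 ± 0.30), E4 (1.14 ± 0.63) and C3 (1.09 ± 0.29), and its maps in pairs of datasets had Spearman rho between 0.596 and 0.683. Of its 7 measured genes 6 differed among positions and 7 when adjusted over the list alone. Among them Syndig1l, a gene of striatal synapses, reached 2.48 ± 0.50 at D9, and Rasd2, a striatal small GTPase, reached 1.77 ± 0.48 there. The cortical list was highest at F8 (0.91 ± 0.30) and F9 (0.89 ± 0.26), with rho between 0.646 and 0.695 and 3 of 4 genes called, or 4 adjusted over the list alone. Its member Mef2c, a transcription factor, peaked at G3 (1.16 ± 0.56). The thalamus list was highest at C6 (1.48 ± 0.09) and C7 (1.38 ± 0.21, n = 2), with rho between 0.256 and 0.531, 2 of 4 genes called and 3 adjusted over the list alone. The thalamic transcription factor Tcf7l2 reached 2.58 ± 0.25 at C6, and Prkcd, a protein kinase C gene, 2.02 ± 0.20 at C5. In row D, where the order of the arrays of dataset 2 was in doubt, Tcf7l2 varied widely between datasets, as at D5 (2.38 ± 2.27). The hypothalamus list was highest at B7 (1.01 ± 0.36), with rho between 0.207 and 0.530, 2 of 3 genes called and 2 adjusted over the list alone, and the appetite peptide gene Cartpt reached 1.41 ± 0.64 at B6. The choroid plexus list peaked at E7 (2.06 ± 0.88), with rho between -0.0871 and 0.323, 1 of 3 genes called, Ttr, and 1 adjusted over the list alone.

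The myelin list was highest at D4 (0.79 ± 0.15) and C4 (0.69 ± 0.10), with rho between 0.614 and 0.732 and 2 of 4 genes called, also 2 adjusted over the list alone. Its 2 called genes, the chaperone gene Cryab (1.42 ± 0.23) and Qdpr (1.14 ± 0.07), an enzyme of biopterin recycling, both peaked at C4. Of the immediate early genes 2 of 6 were called, or 3 adjusted over the list alone, and Arc, a synaptic activity gene, was highest at F9 (1.36 ± 0.42) and lowest at B6 (-1.50 ± 0.74). Of the ribosomal protein genes 29 of 73 were called, or 49 adjusted over the list alone, with the list mean highest at B5 (0.48 ± 0.06, n = 2). The oxidative phosphorylation list had 8 of 55, or 17 adjusted over the list alone, with the highest mean at C8 (0.47 ± 0.28). The astrocyte list had 3 of 6 called (4 adjusted over the list alone), among them the glycolytic gene Aldoc, highest at C8 (0.74 ± 0.41). The hippocampus list had 1 of 4 called (Bok, 2 adjusted over the list alone). The inhibitory neuron list had 1 of 3 (Sst, 2 adjusted over the list alone) and the pan-neuronal list 1 of 3 (Nefl, 2 adjusted over the list alone). The heat shock list had 1 of 6 (Hspa5, 2 adjusted over the list alone). The meninges list had 1 of 9 and the blood list 1 of 4, each also 1 adjusted over the list alone. Their called genes were the growth factor gene Igf2, highest at E7 (2.09 ± 0.59), and the globin gene Hbb-b1, highest at C8 (0.81 ± 0.79). In the remaining lists no measured gene was called, over all genes or adjusted over the list alone. Measured were 5 of 18 cerebellar, 6 of 15 midbrain and hindbrain, 2 of 6 olfactory bulb and 4 of 15 microglial genes. For the vascular, ependymal and immature neuron and proliferation lists they were 5 of 15, 4 of 9 and 5 of 9. The markers not measured could not be called. None of the 8 genes of the septum and cholinergic list was measured.

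The second comparison set rows A-B (18 positions) against rows F-G (17 positions), opposite ends of the section. Dataset 1 had only 11 of the positions of rows A-B and dataset 3 only 14 of those of rows F-G, so the datasets averaged partly different positions. Gap43 was 1.49 ± 0.21 higher in rows A-B (2.81-fold, adjusted p = 0.0349), as were Ndn, by 1.32 ± 0.13 (adjusted p = 0.0349), and Klhl13, a ubiquitin ligase adaptor, by 1.31 ± 0.20 (adjusted p = 0.0442). Vxn fell by 2.38 ± 0.39 (5.22-fold, adjusted p = 0.0212), Dkk3 fell by 1.96 ± 0.09 (3.89-fold, adjusted p = 0.0139) and Egr1 fell by 1.78 ± 0.44 (adjusted p = 0.0473). Nrgn (-1.65 ± 0.30), the corepressor Rcor3 (-1.63 ± 0.06), Osbpl1a (-1.55 ± 0.06), which binds sterols, and the list member Arc (-1.54 ± 0.25) were also lower. All of these had the same sign in 3 of 3 datasets.

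Of all genes 17 passed, 4 higher and 13 lower in rows A-B, and 1409 had an unadjusted p under 0.05. The following were chosen after their values were seen. Igfbp4 (-1.52 ± 0.27), the transcriptional repressor Zbtb18 (-1.37 ± 0.12), Chn1 (-1.29 ± 0.10) and the calcium-binding gene Cabyr (-1.21 ± 0.09) also passed, and the 4th higher gene was the clone vc0319, which has no symbol (3.09 ± 0.17, adjusted p = 0.00282). Without centring of the arrays 9 genes were higher and 15 lower. The count was 0 with quantile normalization, 1 with the floor values kept, 154 over rows measured on every array, and 1, 0 and 2 without datasets 1, 2 and 3 in turn. By the median array of each dataset, rows A-B had a wider spread than rows F-G, 0.327 ± 0.049 against 0.256 ± 0.028. By the same measure they had more values missing or at the floor, 2.03% against 1.09%. The single arrays with the most such values were in rows F-G of dataset 3, however: G8 (41.5%), G3 (20.3%) and G6 (15.1%).

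With the preset correlation 8 of 22 lists differed between rows A-B and rows F-G. The cortical list was lower by -1.10 ± 0.22 (adjusted p = 2.5e-15, but adjusted p = 0.412 with an estimated correlation), with 1 of 4 genes called, Vxn, and 3 adjusted over the list alone. Its member Fezf2, a gene of deep-layer neurons, differed by -1.15 without passing. The immediate early list was lower by -0.54 ± 0.15 (adjusted p = 2.9e-05, but adjusted p = 0.460 with an estimated correlation), with 2 of 6 genes called and 4 adjusted over the list alone. The hippocampus list was lower by -0.40 ± 0.07 (adjusted p = 0.00448, but adjusted p = 0.412 with an estimated correlation), with 0 called and 1 adjusted over the list alone. The hypothalamus list was higher by 0.58 ± 0.13 (adjusted p = 6.3e-08, but adjusted p = 0.460 with an estimated correlation), with 1 of 3 called, Ndn, and 2 adjusted over the list alone. The ribosomal list was higher by 0.24 ± 0.08 (adjusted p = 6.2e-18, but adjusted p = 0.412 with an estimated correlation), with 67 of 73 genes above 0. The inhibitory neuron list (0.39 ± 0.22, adjusted p = 0.0160), the striatal list (0.17 ± 0.08, adjusted p = 0.0274) and the oxidative phosphorylation list (0.05 ± 0.03, adjusted p = 0.0259) were higher, but had an adjusted p = 0.412, 0.460 and 0.412 with an estimated correlation. Over all genes 0 of the ribosomal, inhibitory neuron, striatal and oxidative phosphorylation genes were called, and adjusted over the list alone 0, 1, 1 and 0. Among lists not called, the thalamus list averaged 0.03 because Tcf7l2 (0.97) and Prkcd (-0.92) went opposite ways. The vascular list had a median of 0.08 and a mean of -0.11, and the choroid plexus list a median of 0.12 and a mean of -0.10, with the test of each opposite in sign to the mean and to the median in turn. The heat shock list had a median of -0.04 and a mean of -0.01, and its test went up. Without dataset 1 there were 5 lists.

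**Figure D2:**
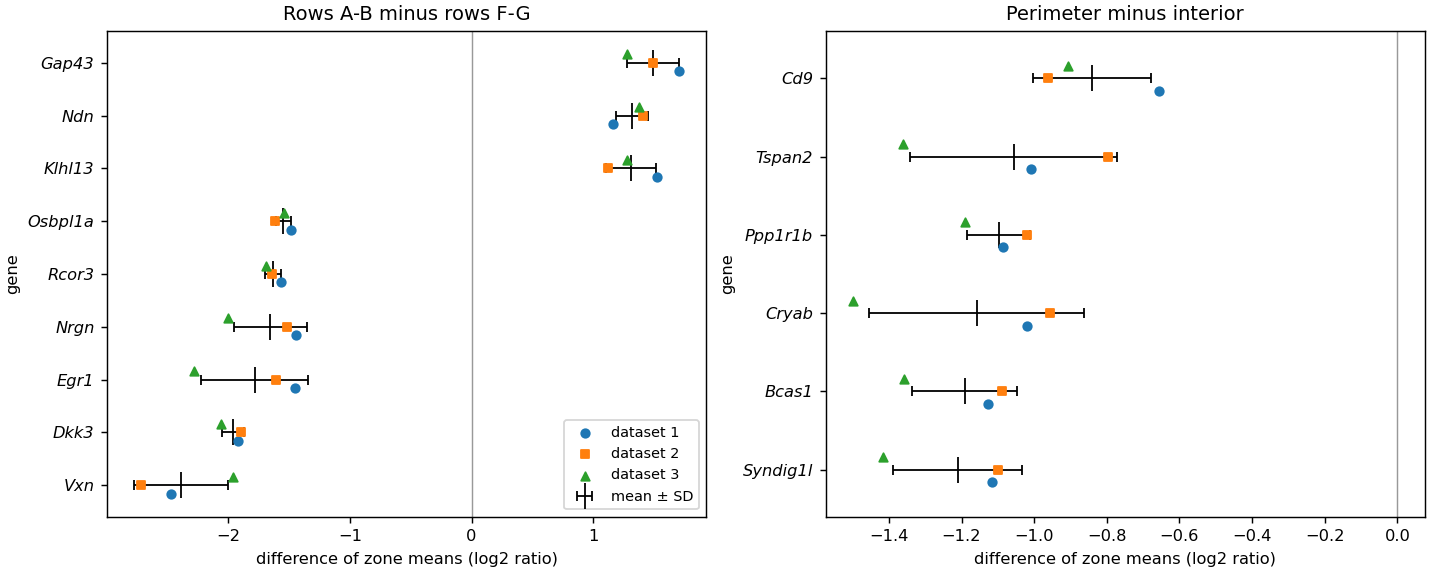
Difference of zone means (x axis, log2 ratio) for up to 6 passing genes in each direction (y axis), list members added to them left out, rows A-B minus rows F-G on the left and perimeter minus interior on the right. Circles, squares and triangles are datasets 1, 2 and 3, and the black bar is the mean ± SD, from -2.38 for Vxn to 1.49 for Gap43 on the left and from -1.21 for Syndig1l to -0.84 for Cd9 on the right.

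The third comparison set the middle columns 5-7 (21 positions) against the outer columns 1-3 and 9-11 (33 positions). The genes nearest to passing were Arpp21, a cyclic AMP-regulated phosphoprotein of striatal neurons (-0.91 ± 0.10, adjusted p = 0.0691), and the calcium signalling genes Caln1 (-0.97 ± 0.15, adjusted p = 0.0701) and Camk4 (-1.03 ± 0.19, adjusted p = 0.0701). In the other direction they were Vat1, a vesicle protein gene (0.80 ± 0.10, adjusted p = 0.0739), the adhesion gene Emb (0.61 ± 0.07, adjusted p = 0.0868) and Dbi, which carries acyl-CoA (0.65 ± 0.10, adjusted p = 0.0868). With limma 0 genes passed, and 2054 had an unadjusted p under 0.05 where 780.4 would be expected.

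In dataset 2 the arrays of row D, columns 1 to 7, matched the other datasets better in reverse order. Over 300 genes their mean correlation with the other datasets was -0.0577 at the labelled positions and 0.464 in reverse. The labels were kept. In a comparison chosen after this was seen, without the 6 arrays concerned, 46 genes passed, 16 higher and 30 lower in the middle columns. Vat1 (0.88 ± 0.14, adjusted p = 0.0244), Igfbp5, which binds growth factors (0.74 ± 0.08, adjusted p = 0.0279), Prkcd (0.74 ± 0.03, adjusted p = 0.0244) and Bcas1 (0.73 ± 0.12, adjusted p = 0.0316) were highest, with Dbi (0.70 ± 0.06) and Emb (0.67 ± 0.06). Ppp1r1b (-1.74 ± 0.41, adjusted p = 0.0244), Egr1 (-1.36 ± 0.14, adjusted p = 0.0153), Vxn (-1.26 ± 0.24, adjusted p = 0.0234) and Camk4 (-1.10 ± 0.19, adjusted p = 0.0234) were lowest, with Rcor3 (-1.09 ± 0.23) and Caln1 (-1.09 ± 0.07). Quantile normalization gave 60 genes, 19 higher and 41 lower, and rows measured on every array gave 201. Limiting values to within 3 of 0 gave 8 genes, and the positions common to all datasets gave 5. There were 21 genes without dataset 1 and 35 without dataset 2.

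**Figure D3:**
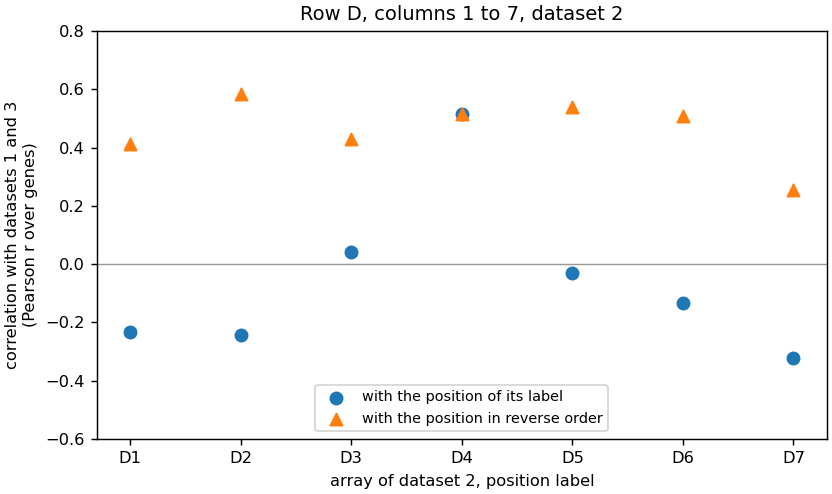
Pearson correlation over 300 genes (y axis) of each array of row D, columns 1 to 7, of dataset 2 (x axis, position label) with the means of datasets 1 and 3 at the labelled position (circles) and at the position in reverse order (triangles). At D2 the correlation is -0.242 as labelled and 0.584 in reverse, and D4, the middle of the order, is the same in both (0.517).

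In the middle columns 8 of 22 lists differed with the preset correlation. The striatal list was lower by -0.74 ± 0.20 (adjusted p = 1.4e-24, but adjusted p = 0.492 with an estimated correlation), with 0 of 7 genes called over all genes and 7 adjusted over the list alone, Ppp1r1b at -1.60 ± 0.52 among them. The immediate early list was lower by -0.32 ± 0.08 (adjusted p = 1.8e-05, but adjusted p = 0.528 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Its median was only -0.11, with Egr1 at -1.24, Arc at -0.57 and 1 of 6 genes above 0. The cortical list was lower by -0.41 ± 0.27 (adjusted p = 8.0e-04, but adjusted p = 0.548 with an estimated correlation), with 0 called and 2 adjusted over the list alone. The thalamus list was higher by 0.48 ± 0.30 (adjusted p = 8.0e-04, but adjusted p = 0.548 with an estimated correlation), with 0 called and 2 adjusted over the list alone. The astrocyte list (0.19 ± 0.03, adjusted p = 8.0e-04) and the myelin list (0.27 ± 0.04, adjusted p = 8.3e-04) were higher, each with an adjusted p = 0.492 with an estimated correlation. In these lists 0 genes were called, and 4 of 6 and 2 of 4 adjusted over the list alone. The ribosomal list was higher by 0.12 ± 0.03 (adjusted p = 1.4e-09, but adjusted p = 0.492 with an estimated correlation), with 67 of 73 genes above 0. The heat shock list was higher by 0.16 ± 0.08 (adjusted p = 0.00792, but adjusted p = 0.528 with an estimated correlation). In the ribosomal and heat shock lists 0 genes were called, and 0 adjusted over the list alone. The microglia list, not called, had a median of -0.04 and a mean of 0.00324.

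The fourth comparison set one side of the section, columns 1-5, against the other, columns 7-11, in mirror pairs. Megf6, a gene with epidermal growth factor repeats (0.35 ± 0.04), and the sphingosine phosphate receptor S1pr3 (-0.25 ± 0.05) were among the genes with the smallest p, and neither passed (adjusted p = 0.958 for both). The others were Lcn11, Otof, Pkp2 and Chst10, none beyond 0.35 in size. With limma 0 genes passed and 522 had an unadjusted p under 0.05, fewer than the 780.4 expected. None of the 22 lists was called, and the striatal list differed by 0.01 ± 0.04 between the sides. Without the array of G8 in dataset 3 there were 2 lists called, and without datasets 1 and 3 in turn 2 and 3. For the thalamus, pan-neuronal, microglia and blood lists the median, the mean and the test differed in sign.

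The last zone comparison set the perimeter of the grid (26 positions) against its interior (42 positions). Syndig1l was lower at the perimeter by -1.21 ± 0.18 (2.31-fold, adjusted p = 0.00614) and Ppp1r1b by -1.10 ± 0.09 (adjusted p = 0.00564). The oligodendrocyte genes Bcas1 (-1.19 ± 0.15, adjusted p = 0.00564), Cryab (-1.16 ± 0.30, adjusted p = 0.0266) and the tetraspanin genes Tspan2 (-1.06 ± 0.29, adjusted p = 0.0266) and Cd9 (-0.84 ± 0.16, adjusted p = 0.0266) were lower as well. The list member Qdpr differed by -0.76 ± 0.13 (adjusted p = 0.0298). All 17 genes that passed were lower at the perimeter, in 3 of 3 datasets for those named, and 2089 had an unadjusted p under 0.05. Among those chosen after their values were seen were Gatm, an enzyme of creatine synthesis (-0.80 ± 0.13), the stress response gene Ndrg1 (-0.80 ± 0.04), the fatty acid desaturase Scd2 (-0.80 ± 0.19), the growth factor gene Tgfa (-0.79 ± 0.12), the ferritin gene Fth1 (-0.73 ± 0.01), the septin gene Septin4 (-0.71 ± 0.05) and the lysophosphatidic acid receptor Lpar1 (-0.65 ± 0.05). By the median array of each dataset, the spread was 0.300 ± 0.064 at the perimeter and 0.297 ± 0.051 inside. By the same measure 1.85% and 1.44% of values were missing or at the floor. The single arrays with the most such values, G8, G3 and G6 of dataset 3, were all at the perimeter (41.5%, 20.3% and 15.1%). The count was 0 without the dataset as a block, 4 with the floor values kept, 56 with quantile normalization (4 higher, 52 lower) and 128 over rows measured on every array (34 higher, 94 lower). Each row of the table on its own gave 30. Without dataset 1 it was 58 (8 higher, 50 lower), and without dataset 2 it was 0.

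At the perimeter 7 of 22 lists differed with the preset correlation, all lower. The striatal list was lower by -0.48 ± 0.06 (adjusted p = 3.8e-19, but adjusted p = 0.584 with an estimated correlation), with 2 of 7 genes called and 5 adjusted over the list alone. The myelin list was lower by -0.57 ± 0.11 (adjusted p = 6.9e-13, but adjusted p = 0.584 with an estimated correlation), with 2 of 4 genes called and 3 adjusted over the list alone. The ribosomal list was lower by -0.19 ± 0.08 (adjusted p = 5.4e-22) and the oxidative phosphorylation list by -0.16 ± 0.07 (adjusted p = 1.0e-13), each with an adjusted p = 0.584 with an estimated correlation. In these 1 of 73 and 3 of 55 genes lay above 0, and 0 were called over all genes or adjusted over the list alone. The thalamus list (-0.44 ± 0.31, adjusted p = 4.0e-04), the microglia list (-0.21 ± 0.09, adjusted p = 0.00638) and the heat shock list (-0.14 ± 0.09, adjusted p = 0.0207) were lower, each with an adjusted p = 0.584 with an estimated correlation. In these 3 lists 0 genes were called over all genes, and 2, 2 and 1 adjusted over the list alone. The meninges list differed by 0.06 ± 0.12 and the vascular list by 0.16 ± 0.08, and neither was called. The pan-neuronal list had a median of 0.05 and a mean of -0.00719, and the immature neuron and proliferation list a median of -8.1e-05 and a mean of 0.06, and neither was called.

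The last question was which genes followed the map of a list across datasets. The map of the striatal list was followed by Tgfa (mean r = 0.688 ± 0.078, adjusted p = 6.6e-26), which itself reached 2.15 ± 0.32 at D9, and by the actin-binding gene Nexn (0.535 ± 0.100), the mitochondrial import receptor Tomm70a (0.528 ± 0.021), the homeobox gene Meis2 (0.517 ± 0.037), the phosphatase inhibitor Ppp1r2 (0.510 ± 0.031), the GTPase Rragd (0.506 ± 0.103), Ivns1abp (0.506 ± 0.040) and Caln1 (0.484 ± 0.147). Rows averaged for several of these genes agreed poorly. The 2 rows correlated at 0.0814 for Ppp1r2, 0.224 for Tomm70a and 0.326 for Rragd, but at 0.607 for Meis2. The 3 rows correlated at between -0.143 and 0.555 for Nexn and between -0.0588 and 0.436 for Ivns1abp. Map following was not tested row by row. Of the striatal list's own members Ppp1r1b followed the rest of the list most closely (0.701) and Bcl11b, a transcription factor, did not pass (0.153). The cortical list was followed by Dkk3 (0.678 ± 0.041), Igfbp4 (0.674 ± 0.036), the nuclear factor Nfix (0.668 ± 0.064), Arc (0.667 ± 0.034), Nrgn (0.657 ± 0.089), Rcor3 (0.656 ± 0.076), Egr1 (0.656 ± 0.060) and Zbtb18 (0.630 ± 0.093).

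The myelin list was followed by Bcas1 (mean r = 0.726 ± 0.050, adjusted p = 1.2e-20), Dbndd2 (0.684 ± 0.121), Scd2 (0.630), Tspan2 (0.628), Gatm (0.623), Fth1 (0.619), the ubiquitin ligase Rnf13 (0.610) and Daam2 (0.608), a gene of Wnt signalling. Its member Mbp, myelin basic protein, did not pass (0.100, adjusted p = 0.611). The hypothalamus list was followed by Peg3 (0.586 ± 0.036), Gaa (0.585 ± 0.090), which encodes a lysosomal glucosidase, the imprinted gene Impact (0.572 ± 0.130), Gap43 (0.551), Tmsb10 (0.543), Timp2 (0.540), Bex2 (0.532) and Vat1 (0.519). None of its 3 own members passed, Cartpt having the highest mean r (0.224), and without dataset 2 Peg3, Gap43, Bex2, Timp2 and Vat1 no longer passed. That map rested on Ndn: with Ndn left out of it, a setting chosen after the data were seen, 0 genes passed with limma (734 with an unadjusted p under 0.05). Without dataset 3 Ivns1abp and Caln1 no longer followed the striatal list.

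In all 352 genes followed the striatal list (274 positively, 78 negatively), 660 the cortical list (297 and 363), 646 the myelin list (490 and 156) and 437 the hypothalamus list (292 and 145). Without datasets 1, 2 and 3 in turn the counts were 226, 102 and 23 for the striatal list, 94, 176 and 329 for the cortical list, 301, 265 and 128 for the myelin list and 74, 10 and 162 for the hypothalamus list. The cortical count was 181 without Vxn in the list map, the myelin count 411 without Qdpr, and the hypothalamus count 689 without Cartpt. The striatal count was 158 with Spearman correlation and 529 without the 6 arrays of row D in dataset 2. Of the 768 genes that differed among positions, 577 (75.1%) followed at least 1 of the 4 lists positively, against 7.80% of all genes. Both tests use the same arrays and need a map that repeats across datasets. Much of this contrast may therefore come from how the 768 genes were chosen.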

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

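The tests of row D in dataset 2 and the test of a general induction of immediate early genes by handling were chosen only after the results were seen.

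Of the 6 control features named Ambion with values in datasets 1 and 2, which belong to no comparison here, 4 differed between datasets 1 and 2 by more than any of the 11 plant, ATCC or blank control features, where the largest distance between medians was 1.67 (log2). Ambion1 differed by 14.2, Ambion2 by 15.0, Ambion3 by 2.51 and Ambion4 by 1.97. The median of Ambion2 was 14.54 in dataset 2 and -0.43 in dataset 1. These features had no values in dataset 3. No explanation was tested for them. The array weights of limma were lowest for G9 of dataset 3 (0.105), G3 of dataset 2 (0.120) and G8 of dataset 3 (0.168).

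In dataset 2, row D, columns 1 to 7, did not match the same positions of the other datasets. Of the 5040 possible orders of these 7 arrays the exact reverse matched best, at rank 1, with a mean correlation of 0.464 against -0.0577 as labelled, over 300 genes chosen from the other datasets alone. The same reversal of columns 1 to 7 gained nothing in rows C and E: their match changed by -0.328 ± 0.103. The reversal therefore did not extend to these neighbouring rows. A section mirrored about its middle column or placed out of line would not reverse columns 1 to 7, so this test cannot decide on either. Reversed labels of the 7 arrays of row D are a candidate explanation only. Those arrays were picked after their match was seen, and the rank uses the same correlations. Whether they were reversed at dissection, labelling or deposition stays open. No biological explanation was tested.

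At the perimeter the ribosomal list was lower by -0.19 ± 0.08 and the oxidative phosphorylation list by -0.16 ± 0.07, calls that were lost with an estimated correlation (adjusted p = 0.584 for both). The spread and missing values of the arrays are argued against as the source, because 92.0% of the ribosomal difference was left after adjustment for them. By the median array of each dataset, both hardly differed between perimeter and interior (spread 0.300 against 0.297, missing or at the floor 1.85% against 1.44%). Missing values were not balanced in single arrays: the highest shares, at G8 (41.5%), G3 (20.3%) and G6 (15.1%) of dataset 3, were all at the perimeter. The adjustment used these measures only, so it cannot decide on other differences in array quality. For more myelin-rich tissue inside, the ribosomal and myelin list means were correlated across datasets over the 42 interior positions. The mean correlation was 0.0330 ± 0.102, so no link was seen there. This cannot decide on that explanation, because the ribosomal list map itself repeated weakly between datasets (rho between 0.185 and 0.467). The row D arrays of dataset 2, whose order was in doubt, were also included. A shift of abundant transcripts in general may be the source: the 20 measured of 24 housekeeping genes (1 of them, Hspa8, also on the heat shock list) averaged -0.23 ± 0.12, or 120% of the ribosomal difference, although none of them passed by itself. It stays open whether such a shift came from the tissue or from the measurement.

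Egr1 and Arc were lower in rows A-B than in rows F-G, by -1.66 ± 0.30 on average. A general induction of immediate early genes by handling is argued against, because the other 4 measured ones, Fos, Jun, Ier2 and Dusp1, averaged 0.0191 ± 0.17. They went both ways: Ier2 was higher by 0.41 ± 0.12 and Jun by 0.23 ± 0.20, while Dusp1 differed by -0.56 ± 0.44. The 3 rows averaged for Jun correlated only at between -0.223 and 0.0719. An induction of Egr1, Arc and Dusp1 alone stays open. Cortical excitatory neurons may be the source: over the 33 positions of rows C-E their mean correlation with the cortical list was 0.546 ± 0.081. Both genes also followed the cortical list over the whole grid, so this remains a hypothesis found and tested on the same data.

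Chance can be excluded for the position, row and perimeter differences, as far as scattered arrangements, which lack the smoothness of the real zones and maps in space, can show. Among 100 arrangements of the arrays, the real one included, 1 gave as many genes as the real position test (626 of the 7555 genes measured on every array, highest other 37). For rows A-B against rows F-G 1 of 100 did (17, highest other 1), and for the perimeter 1 of 100 (17, highest other 0). For the middle against the outer columns 0 genes passed, so the number passing cannot exclude chance. In its place the genes with an unadjusted p under 0.05 were counted, and 3 of 100 gave as many (2054, highest other 2211). For the sides 87 of 100 did (522, highest other 1450), so chance cannot be excluded. For the maps of the striatal, cortical, myelin and hypothalamus lists 1 of 100 gave as many genes in each case. The real counts and the highest others were 352 and 91, 660 and 41, 646 and 50, and 437 and 7. Chance can be excluded there with the same limit.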

How the results depend on the processing

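Keeping the floor values, limiting values to within 3 of 0 leaving out arrays of G8 or of row D, and leaving members out of list maps were chosen only after the results were seen. The comparison of the section with whole brain was not run, nor were its alternatives, because the deposited rows were centred. The 768 genes that differed among positions became 366 without the dataset as a block (all 366 shared), 482 with dye orientation in its place, 1161 with quantile normalization and 2573 with array weights, and 213 to 546 without 1 dataset. Not all calls were shared with the 768: 316 of the 546 were without dataset 3, 165 of the 213 without dataset 2, and 277 of the 324 without dataset 1. Over rows measured on every array 473 of 624 were shared. The 17 genes of rows A-B against rows F-G became 10 without the block, 0 with quantile normalization, 154 over rows measured on every array, 5 over rows measured on at least 50% of arrays, 1 with the floor values kept, 26 with values limited, 33 over positions measured in all 3 datasets, 7 with a linear trend and 0 to 2 without 1 dataset. Without centring they were 24. Of the 17 genes, 10 were among the 154 over rows measured on every array. The 0 genes of the middle columns became 60 with quantile normalization, 201 over rows measured on every array, 8 with values limited, 46 without the 6 arrays of row D, 5 over positions measured in all 3 datasets and 0 to 35 without 1 dataset. The 17 genes of the perimeter became 0 without the block, 56 with quantile normalization (4 higher, 52 lower), 128 over rows measured on every array (34 higher, 94 lower), 30 with every row on its own, 4 with the floor values kept and 0 to 58 without 1 dataset (8 higher and 50 lower without dataset 1). Of the 17 perimeter genes, 10 were among the 128 over rows measured on every array. Between the sides 0 genes passed under every alternative run. The lists called fell from 8, 8 and 7 to 0 with an estimated correlation for rows, middle columns and perimeter. The 8 lists of the rows comparison ranged from 5 to 10 without 1 dataset. Those of the middle columns became 9, 11 and 6 without datasets 1, 2 and 3 in turn, and those of the perimeter 8, 8 and 6. The 0 lists of the sides became 2 without the array of G8 in dataset 3 and 0 to 3 without 1 dataset. Genes following the striatal list became 158 with Spearman correlation and 529 without the 6 arrays of row D. With 1 member left out of the list map, those following the cortical list became 181 (without Vxn), the myelin list 411 (without Qdpr) and the hypothalamus list 689 (without Cartpt) or 0 (without Ndn, where 734 had an unadjusted p under 0.05). Without 1 dataset the counts were 23 to 226 for the striatal, 94 to 329 for the cortical, 128 to 301 for the myelin and 10 to 162 for the hypothalamus list. Lower counts without 1 dataset go with fewer arrays by construction, and for higher counts and the other settings the cause was not tested. No named gene or list that passed, with 928 recomputed values, changed direction, while 187 values of named genes that passed neither before nor after changed sign. The 928 include the F values of the position test, which are never negative and so could not change direction. Lists not called were not recomputed one by one. Of the values recomputed for named genes, the rows comparison had 1144 that stayed on their side of the threshold, 66 that no longer passed and 5 that newly passed. These numbers were 1134, 0 and 61 for the middle columns, 1058, 21 and 7 for the perimeter, 1039, 0 and 0 for the sides, 187, 2 and 0 for positions, 149, 12 and 0 for lists and 321, 15 and 0 for list maps. Signal over background was not used here, so it is not known which genes were near background, and 3 datasets limit every zone comparison.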

Other observations

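The tests of imprinted genes were chosen after Ndn, Peg3 and Impact had been seen, and the matching of arrays to positions and the tests of row differences between other zones were chosen only after the data were seen.

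The imprinted gene Impact reached 1.39 ± 0.18 at A5 and Peg3, also imprinted, 0.85 ± 0.15 at A7, and Gaa peaked at B5 (1.57 ± 0.21, n = 2). Hspa5, a chaperone of secretory cells, was highest at B7 (0.52 ± 0.17) and A7 (0.50 ± 0.08). Gatm peaked at C4 (1.51 ± 0.15), with Cryab at C4 (1.42) and C8 (1.39 ± 0.52), and Bcas1 was 1.28 ± 0.33 at D8, the mirror image of its peak at D4. Igf2 shared the middle of row E with Ttr, at 1.44 ± 0.33 at E6 and 1.49 ± 0.94 at E8. Nefl was lowest at B6 (-0.92 ± 0.16).

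A hypothesis was that imprinted genes in general follow the hypothalamus map. Of 41 listed genes 23 were measured, and 20 were used after leaving out Ndn, Peg3 and Impact. Their mean z, 0.0791, was higher than in 99.4% of 10000 random gene sets, and Dlk1 (r = 0.403), Grb10 (r = 0.371) and Inpp5f (r = 0.302) carried most of it. The list map itself holds Ndn, which is imprinted. With Ndn left out of the map, the mean z was 0.0272, higher than in 90.7% of random sets, and neither Peg3 (adjusted p = 0.471) nor Impact (adjusted p = 0.329) passed. That map rests on Cartpt and Nr5a1 alone and with limma was followed by 0 genes, with 734 at an unadjusted p under 0.05 where 780.4 would be expected by chance, so this test decides nothing. The hypothesis stays open, since the first value shows no more than that some imprinted genes followed a map partly made of Ndn.

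Each array was also matched to the mean maps of the other datasets. Over all datasets 34 arrays matched their own position best, 81 matched within 1 step of it and 147 (76.6%) matched within 1 step of their own or the mirror position, against 20.3% by chance. There were 94 arrays that matched best 3 or more steps from their own position, and 24 that did so from both their own and the mirror position, 7, 12 and 5 of these in datasets 1 to 3. The difference between rows A-B and rows F-G was also compared between the sides and between the column zones, and with limma 0 genes passed in either, with 408 and 1064 having an unadjusted p under 0.05.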
